A study of Bos taurus with 47 samples.

How the data were processed

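RNA from Holstein cattle was sequenced in 47 libraries that carry 15 tissue labels. Adipose tissue, frontal cortex, heart, ileum, kidney, liver, lung, muscle, rumen and spleen came from the same 4 animals, numbered 3770 and 3773 (males A and B) and 3842 and 3886 (females). Ovary and uterus came from the 2 females. The lactating mammary gland was sampled only in animal 3842, the dry mammary gland only in animal 3886, and lymphocytes only in a further male, animal 4254. In the results, 3842 is the lactating cow and 3886 the dry cow. The series design speaks of 4 individuals and 14 tissues, while the sample labels give 5 animal numbers and 15 labels. The sample labels were used.

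Total RNA was extracted with Trizol, treated with DNase and cleaned on RNeasy columns, per the labels' protocols. Libraries were made with an Illumina TruSeq kit, were pooled by their adaptors, and were sequenced as paired reads of 150 bases on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, STAR, Cufflinks and the cattle assembly UMD3.1. They give no order, settings or gene annotation.

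The authors deposited 1 table of FPKM (fragments per kilobase of transcript and per 1000000 fragments) with 24616 Ensembl gene identifiers and 51 columns. Of these columns, 47 matched a sample by name. The remaining 4 matched no sample and were not used. The muscle column of animal 3770 spells its tissue code with 1 letter more than the sample's title and was matched by its code and animal number. Of the identifiers, 20574 were above 0 in at least 1 used library and 4042 were at 0 in all of them.

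No read counts are part of this table, so the depth of each library is unknown and no counting interval or detection floor was computed. Low FPKM values of a gene fall on steps of whole fragments, and for every pair of libraries the commonest ratio among genes under 0.2 FPKM in both gave a relative depth. It ran from 0.779 (frontal cortex of animal 3842) to 1.56 (kidney of animal 3770). An exact 0 in such a table can also be a failed estimate. In the lymphocyte library, 59 genes were listed at 0 that had at least 1 FPKM in each of the other 46 libraries, and no other library had such a gene.

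The deposited table does not pair its identifiers with gene names. The reference table supplied for this work belongs to another assembly, ARS-UCD2.0, and holds no Ensembl identifiers, so no identifier was matched to a name. No genome was used, and GC content, gene length and chromosome were not examined. The marker and pathway lists fixed beforehand by gene symbol, and the set tests on them, could therefore not be applied. In their place, groups of genes were defined from the libraries themselves, by the tissue in which they were higher. These groups were chosen after the identifiers were seen, describe counts, and were not tested for enrichment. Sets used to describe a comparison were built without the libraries of that comparison.

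Values were taken as log2(FPKM + 1). Differences on this scale understate the change of genes with low values. Linear models were fitted with limma 3.58.1 in R 4.3.3 (moderated variances with an intensity trend, Benjamini-Hochberg adjustment within each contrast, threshold 0.05). For each of the 12 labels with 2 or more libraries, the label's mean was compared with the unweighted mean of the other 14 labels over all 47 libraries, among 16634 genes with at least 1 FPKM in at least 2 libraries. A difference of at least 2 on the log2 scale, or 4-fold, was also required. Heart against muscle (11877 genes) and rumen against ileum (14098 genes) were fitted on 8 libraries each, with a difference of at least 1 required. Males and females were compared in each of 10 tissues over 40 libraries (16503 genes) in 20 cells of 2 libraries that share 1 estimate of the spread, with no minimum difference. A further contrast set each tissue's male minus female difference against the mean difference of the other 9 tissues. The animal is the replicate of sex, so the mean over the 10 tissues was also compared between the 2 males and the 2 females.

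Tissue-enriched genes had a label mean of at least 1 FPKM and at least 4 times the highest mean of every other label, with no test. The lactating and dry glands have 1 library each, so only log2 ratios are given, among 13002 genes with at least 1 FPKM in either library. Library similarity was measured by Spearman and Pearson correlations across genes, which are not replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

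The genes to be described were set by rules of rank within each comparison: the largest differences among called genes, without overlap between the groups' libraries where tissues were compared. The rules ranked genes with a symbol. As no symbols could be had, ranks run over identifiers, and only 4 identifiers are printed, the top 2 per direction between heart and muscle. Other genes are described by their rank and values.

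Libraries of 1 animal share its number, so the numbers pair libraries across tissues. Deviations from the tissue means had a median correlation of 0.182 between libraries of the same animal and of -0.058 between different animals, over the 180 same-number pairs and the pairs that cross animals. For heart and muscle the 4 same-animal correlations ran from 0.196 to 0.371, and for rumen and ileum from 0.102 to 0.224. The fits above carry no block. Fits with the animal as a block were run as alternatives for the tissue comparisons. Animals are nested in sex. In the models of sex the animal entered as a random block with 1 correlation for all genes (0.0384). For the contrast of a tissue's sex difference with the other tissues, which lies within animals, it also entered as fixed terms within sex.

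Each model was tested on simulated data built from the real means and spread, with 100 changed genes for each of 2 fold sizes. Apart from the changed genes, a gene had the same mean in all simulated libraries, and the noise was independent. Each gene also had the same SD in all simulated libraries. The false calls below thus do not cover deviations that libraries of the same animal share, or a tissue with a larger spread. The changed genes were drawn from those above a low mean level and were only raised. The shares called do not cover genes below that level or falls. For a tissue against the others, all of the genes changed by 8-fold and 16-fold were called (100% of each) with 0 false calls among 16634 genes. For heart against muscle, 96% of the genes changed by 4-fold and 100% of those changed by 8-fold were called, with 4 false calls among 11877 genes. For males against females within a tissue, 71% of the genes changed by 2-fold and 97% of those changed by 4-fold were called, with 9 false calls among 16503 genes. For the difference between tissues these were 69% and 95% with 12 false calls, and for animal means 75% and 95% with 8 false calls.

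The pseudocount, the filter on low values, rescaling to a sum of 1000000, quantile normalization, the minimum difference, the reference labels, the animal block and leaving out each animal were set as alternatives before the data were examined. Alternatives chosen after seeing the data leave out 10 libraries that lacked traces of other tissues, the ileum library of animal 3770, the lymphocyte library, or the 10 most abundant identifiers of the lactating library, normalize the glands by quantiles, or use the animal as a block in the models of sex.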

Results

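Transcript levels were measured by RNA sequencing in 47 libraries of Holstein cattle that cover 15 tissue labels. There were 4 libraries, 2 from males and 2 from females, for each of 10 tissues. The males are called A and B here, and the females the lactating cow and the dry cow, after the state of the mammary gland sampled from each. Ovary and uterus had 2 libraries each, and the lactating mammary gland, the dry mammary gland and lymphocytes had 1 each, with no replicate. The deposited values are FPKM for 24616 gene identifiers that are not paired with gene names. Genes are therefore described by the tissues in which they were abundant. The series sets out to compare transcriptomes across tissues. The FPKM of a library summed to between 576130 and 964931, and the depth in fragments is unknown.

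Tissues differed in how many genes reached 1 FPKM and in how far a few genes dominated. Ileum had 13359 ± 297 genes at 1 FPKM or more (SD, n = 4), lung 13103 ± 105 and frontal cortex 12976 ± 47, while muscle had 10124 ± 139. In muscle the 10 most abundant genes held 33.8% ± 0.180 of the summed FPKM, in heart 22.6% ± 2.35, in liver 18.0% ± 0.868 and in rumen 16.8% ± 1.63, against 6.78% ± 0.509 in kidney (SD, n = 4 each). The lactating gland went further, with 9979 genes at 1 FPKM or more and 75.6% of its summed FPKM in 10 genes. The dry gland had 12881 such genes, and its 10 most abundant held 8.08%. FPKM is relative to the library's total, so a few dominant genes lower these counts, which are not numbers of genes expressed. Above 0 FPKM the lactating gland had 15188 genes, the dry gland 16423 and the muscle libraries 14706 to 15195. In every one of the 47 libraries 7310 genes reached 1 FPKM. A mean of at least 1 FPKM was reached in all 15 labels by 7825 genes and in exactly 1 label by 1414 genes.

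**Figure D1:**
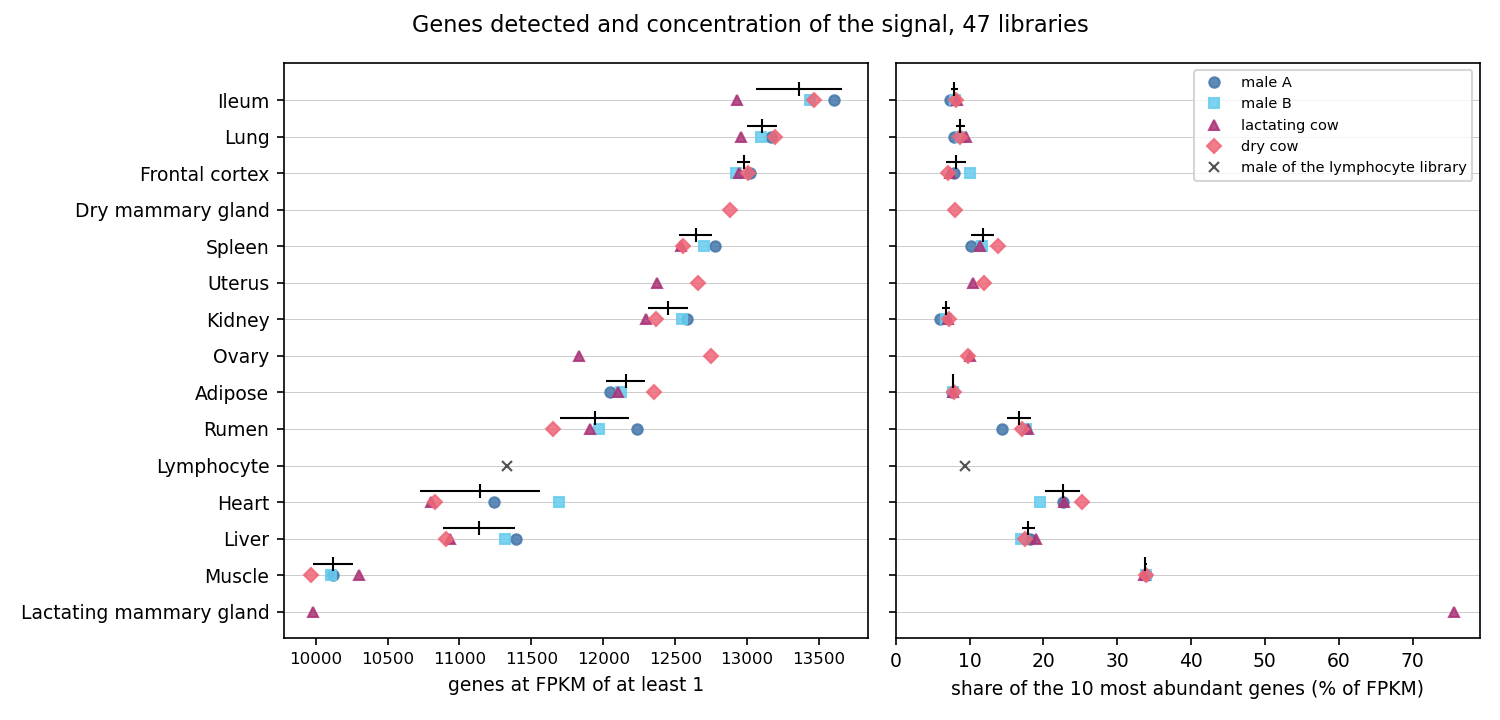
Genes at FPKM of at least 1 (left, count) and share of the 10 most abundant genes in the summed FPKM (right, %) for each of the 47 libraries, by tissue label. Symbols mark the animal, and the black bars above them give the mean and SD of labels with 4 libraries. The lactating gland lies at 9979 genes and 75.6%.

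The tissue label ordered the libraries. All 44 libraries with another library of their tissue had their closest match within that tissue. Spearman correlations across genes had a median of 0.979 within tissues (62 pairs, 0.902 to 0.988) and of 0.760 between tissues (1019 pairs, 0.533 to 0.920). Between tissue means, ovary and uterus correlated at 0.918, adipose tissue and uterus at 0.914, the 2 mammary glands at 0.910 and heart and muscle at 0.896. Spleen was closest to lymphocytes (0.876), ileum to spleen (0.859) and liver to kidney (0.806). Frontal cortex stood farthest apart, and its closest label, ovary, reached 0.722. Over the 40 libraries of the 10 shared tissues, tissue took a median of 93.4% of a gene's variance. The animal took 1.01% and the remainder 5.09%. Sex, with a median of 0.378%, is a part of the animal share. Libraries with no structure at all would give 23.1% for tissue, 7.69% for animal, 2.56% for sex and 69.2% for the remainder. With most of the variance taken by tissue, 7.69% and 2.56% are no measure of chance for animal and sex. Libraries of the same animal deviated together (median correlation 0.182).

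Most libraries also held small amounts of transcripts that belong to other tissues. Genes restricted to liver (18 genes), rumen (10) or muscle (9), with at least 2000 FPKM there and at least 100 times every other label, were followed in the libraries of other tissues, in ppm (parts in 1000000) of their level in the source tissue. In 37 libraries the liver genes stood at 61.0 to 1340 ppm, the rumen genes at 79.6 to 777 ppm and the muscle genes at 90.8 to 869 ppm, as the median over the genes. In the other 10, which are the lymphocyte library and 9 libraries of the lactating cow, they stood at 0 to 33.3, 0 to 6.51 and 3.26 to 76.3 ppm. The labels name no batch, and these 10 libraries were treated as a possible one. They hold no more than 1 library of any tissue, so comparisons could be repeated only among the other 37.

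**Figure D2:**
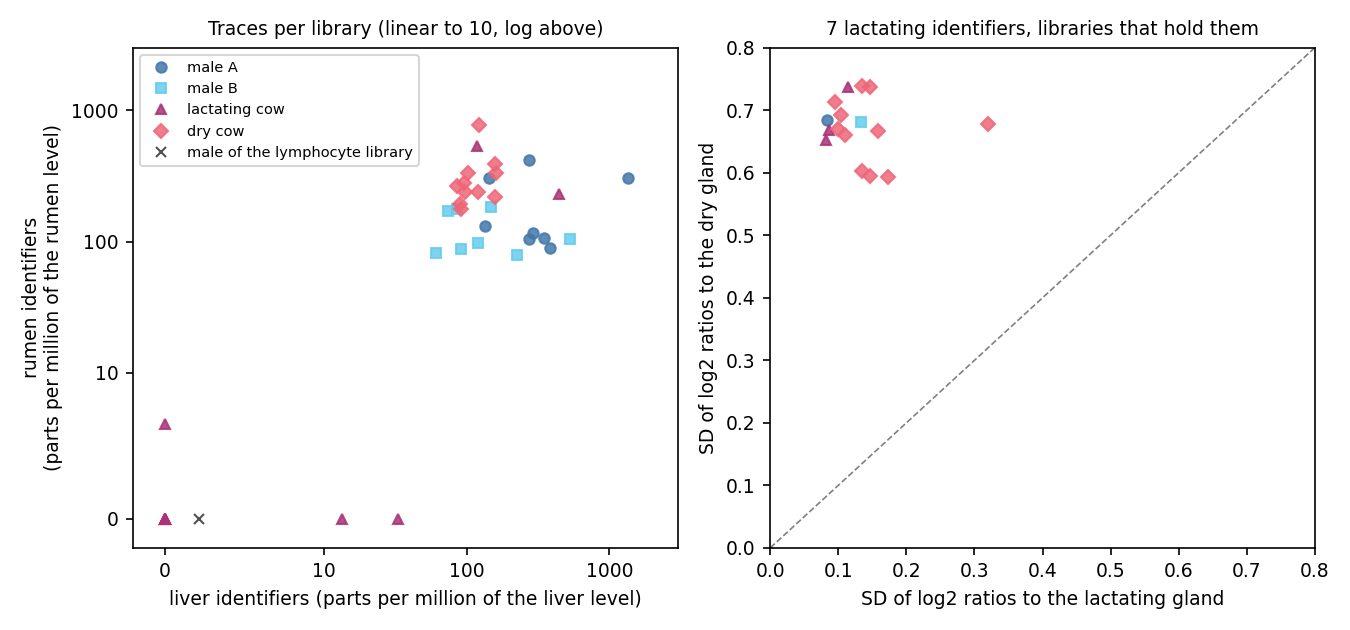
Left, level of liver-restricted genes (x axis) and rumen-restricted genes (y axis) in each library that is neither liver nor rumen, in ppm of the source tissue (axes linear to 10 and log scale above), where 10 libraries lie at or near 0. Right, for the 16 libraries from other tissues that hold all 7 leading genes of the lactating gland, the SD of the log2 ratios of these genes to their lactating levels (x axis) and to their dry levels (y axis), with a dashed line of equality.

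Each tissue was set against the mean of the other 14 labels to find the genes that mark it. Frontal cortex had the most genes at least 4-fold higher, 1904, and 1430 of them were higher in all 4 cortex libraries than in any other library. Muscle had the most genes at least 4-fold lower, 1494, and 658 of them were lower in all 4 muscle libraries than in any other. In ileum and lung most called genes were higher, with 1101 and 946 against 23 and 28 lower ones. The counts come from limma on log2(FPKM + 1) at an adjusted p under 0.05.

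The number of calls on each side depended on the scaling of the libraries. Quantile normalization moved the median of all genes by between -0.47 and 0.60 on the log2 scale, depending on the tissue, and relative to that shift muscle had 752 higher and 373 lower genes in place of 496 and 1494. Higher and lower counts became 1510 and 875 in frontal cortex, 940 and 250 in liver, 855 and 268 in kidney, 721 and 169 in heart, 705 and 282 in spleen, 704 and 73 in ileum, 634 and 63 in lung, and 469 and 96 in uterus. Rescaling each library to the same sum gave 528 and 806 in heart and 597 and 310 in rumen. Of the calls per tissue, between 43.7% (muscle) and 93.8% (rumen) were also called, in the same direction, after quantile normalization, and at least 88.0% after rescaling. The choice of labels also affected the number of lower genes. With only the 10 tissues of all 4 animals in the fit there were 226 lower genes in adipose tissue, 77 in ileum, 120 in lung, 327 in rumen and 347 in spleen, in place of 121, 23, 28, 158 and 172.

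**Figure D3:**
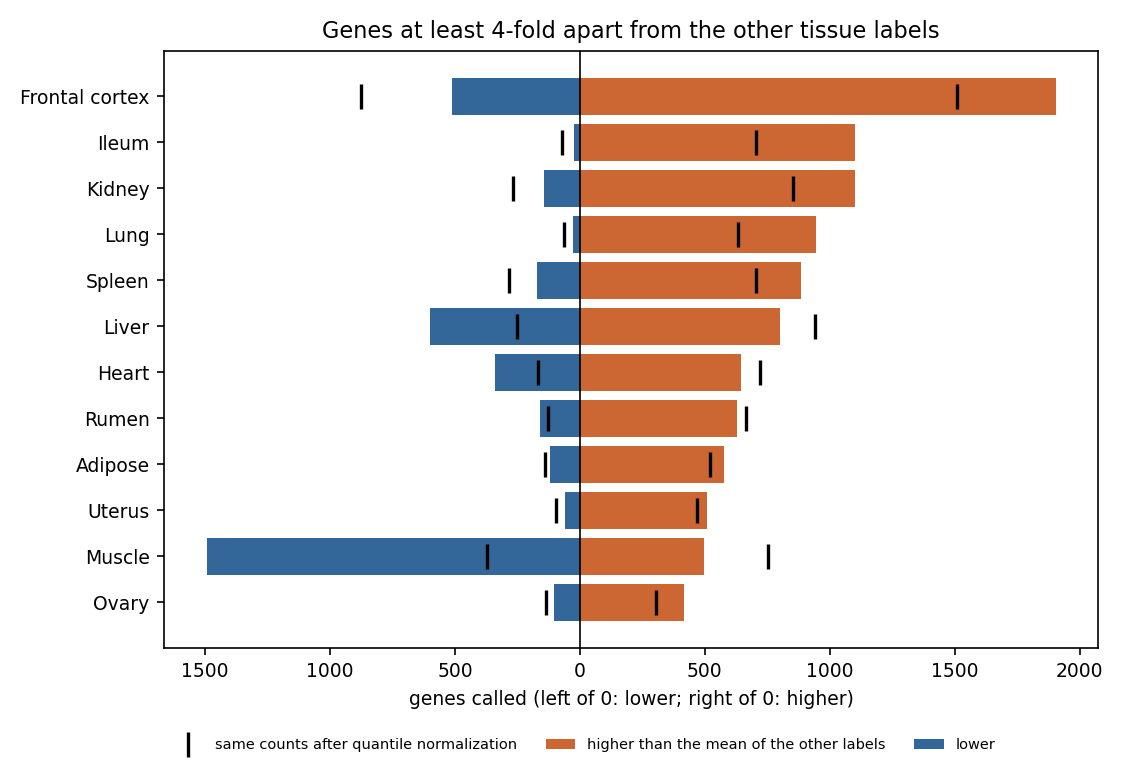
Genes called higher (right of 0) and lower (left of 0) in each tissue against the mean of the other labels, as counts of genes. Bars give the deposited FPKM and black marks the counts after quantile normalization, where muscle moves from 496 higher and 1494 lower to 752 and 373.

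Frontal cortex had 512 lower genes beside its 1904 higher ones. Its leading gene had 16053 FPKM ± 7486 (SD, n = 4) against a mean of 10.9 over the other libraries, a difference of 10.66 ± 0.25 (SE) on the log2 scale. Its 969 tissue-enriched genes, at least 4 times the mean of every other label, were the largest part of the 2656 such genes summed over the labels and held 19.0% ± 1.38 of the cortex FPKM (SD, n = 4).

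Liver and kidney shared part of their profile. Liver had 800 higher and 599 lower genes, and its leading gene reached 34565 FPKM ± 2809 (SD, n = 4) against 4.86 elsewhere. The 242 liver-enriched genes held 37.0% ± 1.54 of the liver FPKM. Kidney had 1100 higher and 144 lower genes, its leading gene had 6331 FPKM ± 377 against 2.17 elsewhere, and its 197 enriched genes held 7.90% ± 0.325. A further 92 genes were enriched in kidney and liver together, the largest group for any pair of labels.

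Heart and muscle, the striated muscle tissues, were dominated by few genes. Heart had 645 higher and 340 lower genes. Muscle had 496 higher genes, and its leading gene by difference had 30270 FPKM ± 2256 (SD, n = 4) against 5.06 elsewhere. The 129 muscle-enriched genes held 40.2% ± 0.566 of the muscle FPKM and the 86 heart-enriched genes (54 after rescaling) 20.5% ± 2.54 of the heart FPKM. The most abundant gene of muscle had 72198 FPKM ± 6634 there, and that of heart, a different gene, had 46057 FPKM ± 15238 in heart. Heart and muscle shared 76 genes enriched in the pair, the second largest group of a pair.

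Rumen, the fermenting forestomach with a stratified lining, had 629 higher and 158 lower genes, and its leading gene had 20600 FPKM ± 3254 (SD, n = 4) against 19.1 elsewhere. Its 203 enriched genes held 21.6% ± 2.90 of the rumen FPKM. Ileum, the last part of the small intestine, had 197 enriched genes that held 6.00% ± 2.66, and its leading gene had 2793 FPKM ± 543 against 2.20 elsewhere. With the animal as a block and without the lymphocyte library, ileum had 44 lower genes in place of 23. In the same libraries without the block it had 37.

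Lung had 112 tissue-enriched genes, 55 with 1 FPKM added to each mean and 171 with a minimum mean of 0.1 FPKM. The 112 held 4.59% ± 0.382 of the lung FPKM, and the leading lung gene had 9241 FPKM ± 534 (SD, n = 4) against 2.31 elsewhere. The lower genes of lung numbered 42 without the lymphocyte library, and 47 in the same libraries with the animal as a block, in place of 28. Spleen had 886 higher and 172 lower genes, 251 lower without the lymphocyte library, 260 lower without that library and the 9 others that lacked traces of liver and rumen genes, and 109 enriched genes with 7.69% ± 2.09 of its FPKM. Adipose tissue had 578 higher and 121 lower genes and 64 enriched genes with 3.33% ± 0.345. Ovary had 416 higher and 103 lower genes. Uterus had 509 higher and 61 lower genes. With 2 libraries each, these rest on the spread shared with the other labels, and without the dry cow the lower genes were 200 in ovary and 105 in uterus, while without the lactating cow ovary had 66. The leading ovary gene had 383 FPKM in one ovary and 7840 in the other.

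Heart was compared with muscle directly to separate the striated tissues. Heart was higher in 3120 genes and muscle in 811. The largest rise in heart was ENSBTAG00000006424, with 27480 FPKM ± 3751 in heart against 3.14 to 6.95 in muscle (SD, n = 4 each), and the next was ENSBTAG00000045789, with 11900 FPKM ± 1563 against 3.42 to 4.32. On the muscle side, ENSBTAG00000021218 lay between 20540 and 25270 FPKM in muscle and between 0.142 and 3.48 in heart, and ENSBTAG00000010880 lay between 15830 and 17330 FPKM in muscle and between 0 and 3.19 in heart. What these genes encode is not given in the sources used here.

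The differences of those genes in log2 (heart minus muscle) were 12.26 ± 0.19, 11.24 ± 0.12, -12.96 ± 0.35 and -12.61 ± 0.37 (SE), with limma adjusted p of 1.376e-12, 1.686e-13, 1.062e-10 and 2.001e-10, and each was separated in 4 of 4 libraries. The low side of both muscle genes lay near the traces of other tissues found in most libraries, but both belong to the genes that define these traces. The 9 genes restricted to muscle, both included, stood in heart at 31.6, 186, 195 and 243 ppm of their muscle level. No trace level was computed for genes restricted to heart. Of the called genes, 3073 of the 3120 and 785 of the 811 had no overlap between the 4 heart and 4 muscle libraries. Genes higher in any of 10 other tissues were more often higher in heart than genes at large (26.3%), from 32.9% for frontal cortex to 51.1% for lung (284 of 556), and except for spleen (4.35%) also more often higher in muscle (8.13% to 15.5% against 6.83%). No difference between these groups was tested. Quantile normalization shifted the median of all genes by -0.43 and left 1586 genes higher in heart and 1379 in muscle, and rescaling gave 2202 and 1172. Among the 37 libraries that held traces of liver and rumen genes, without the heart library of the lactating cow, there were 3250 and 765.

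Rumen and ileum were compared as the sampled parts of the digestive tract. Ileum was higher in 4396 genes and rumen in 980. Of the gene groups by tissue, the genes higher in spleen, the blood-filtering lymphoid organ, had the largest share higher in ileum. It was 714 of 898 (79.5%), with 27 (3.01%) higher in rumen, against 31.2% and 6.95% of all genes tested. No difference between these groups was tested. Genes higher in lung (429 of 894, 48.0%), liver (263 of 605, 43.5%) and kidney (383 of 934, 41.0%) were also more often higher in ileum than genes at large, but so they were in rumen (13.1%, 15.9% and 14.6%). The leading rumen gene had 20600 FPKM ± 3254 (SD, n = 4) against 3.93 in ileum, and the leading ileum gene had a mean of 2793 FPKM and lay between 0 and 0.289 in rumen.

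Libraries did not overlap for 944 of the genes higher in rumen and 4160 of those higher in ileum. Quantile normalization shifted the median of all genes by 0.62 and brought the counts to 1875 in rumen and 2077 in ileum. Among libraries with traces of liver genes, without the ileum library of the lactating cow, the counts were 994 and 4921.

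The lactating gland of 1 cow was set beside the dry gland of another to describe milk production. The lactating library was taken over by 7 genes, at 157800, 150700, 132800, 108900, 62180, 61750 and 28400 FPKM. In the dry gland these stood at 1636, 1671, 2074, 3456, 420, 597 and 354 FPKM. Among 13002 genes, 108 were at least 4-fold higher in the lactating gland and 3437 at least 4-fold higher in the dry gland, with a median log2 ratio of -1.50. The 15 genes with the largest rise in lactation had log2 ratios of 5.61 to 7.21, and for 8 of them ovary was the highest of the other tissues, with 0.441 to 119.5 FPKM. The ovary library of the dry cow held the 7 leading lactating genes at 1405 ppm of their lactating level. For another 4 it was adipose tissue, which lay above the lactating gland for 2 of them.

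Genes of uterus (266 of 445, 59.8%), adipose tissue (301 of 517, 58.2%), lung (392 of 770, 50.9%) and ovary (162 of 321, 50.5%) were most often at least 4-fold higher in the dry gland, against 26.4% of genes at large. Only genes of muscle (24.6%) and heart (17.8%) lay below that share among 12 tissues. Of the 15 largest falls in lactation, 5 had rumen as the highest of the other tissues, above the dry gland for 1 of them. The counts depended on the scaling. Rescaling to the same sum gave 87 genes higher in the lactating and 6058 in the dry gland. Quantile normalization shifted the median ratio by 1.47 and gave 448 and 429. It changed the sign of the ratio for 5654 of the 13002 genes (43.5%). There is no replicate, and stage and cow cannot be separated. The same 2 cows differed 4-fold in 8 to 254 genes one way and 6 to 381 the other way in their 12 other tissues.

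Males and females were compared within tissues to see whether sex changes a tissue's profile. With all libraries, ileum had the most calls, with 2517 genes higher in males and 1488 higher in females, followed by adipose tissue with 846 and 1088. The order turned without the lactating cow (1068 calls in ileum and 1150 in adipose tissue) and without the 10 libraries that lacked traces (1180 and 1241). Both settings take the same library, that of the lactating cow, from ileum and from adipose tissue, so they are not separate checks there. Heart had 510 and 36, lung 215 and 114, kidney 154 and 41, spleen 98 and 71, muscle 63 and 35, liver 54 and 27, frontal cortex 34 and 7, and rumen 34 and 27. The median size of a called difference was 0.85 in ileum and 0.85 in adipose tissue on the log2 scale, and 1533 and 710 of the calls were at least 2-fold. Each group has 2 animals.

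In ileum, the shares of called genes differed between the genes that mark other tissues, which was not tested. Of all genes tested, 9.02% were called higher in females and 15.3% higher in males, with a median male minus female difference of 0.14 (log2). Of the genes higher in kidney, 32.9% (372 of 1132) were called higher in females and 6.01% (68) in males, and their median was -0.19, or -0.20 to -0.18 without each animal in turn. For genes higher in rumen these were 32.5% (217 of 667) and 5.55% (37), with a median of -0.11 (-0.16 to -0.08), and for genes higher in liver 30.0% (248 of 827) and 4.35% (36), with a median of -0.08 (-0.13 to -0.03). Most genes of each set were called in neither direction. Genes higher in spleen had a median of 0.34 in ileum, with 219 of 953 higher in males and 49 in females, but of 0.05 without the lactating cow, where all genes had 0.03, and of 0.65 without the dry cow, where all genes had 0.27. Their median was also above that of all genes in liver (0.32 against 0.09, and 0.17 against 0.09 without male A), rumen (0.29 against 0.10) and heart (0.30 against 0.15, and 0.20 against 0.08 without male B), and below it in lung (-0.14 against 0.01) and adipose tissue (-0.18 against -0.07). Without male A both lung values were 0.00, and adipose tissue had 0.00 against -0.05. Genes higher in adipose tissue had a median of 0.47 in ileum, which was 0.23 without male A, 0.18 without the lactating cow and 0.80 without the dry cow. In heart these had a median of 0.45, or 0.24 without male B. They also lay above all genes in the remaining tissues with that set, but not always without an animal. In liver they had 0.12 against 0.09 (0.07 against 0.10 without the lactating cow). In spleen they had 0.13 against 0.05 (0.04 against 0.07 without male B). In rumen they had 0.34 against 0.10 (0.05 against 0.07 without male A), and in kidney 0.24 against 0.03. In adipose tissue, genes higher in uterus had a median of -0.31 (-0.20 without the dry cow), with 101 of 561 higher in females, and genes higher in heart a median of 0.13 (0.07 without male A), with 123 of 651 higher in males.

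These counts rested on few animals. Fitted alone, 2 against 2, no tissue gave a limma call, while 1120 to 3494 genes per tissue had an unadjusted p under 0.05, 2802 in ileum and 3494 in adipose tissue. With the spread shared over tissues, 5828 genes in ileum and 3997 in adipose tissue had an unadjusted limma p under 0.05. Ileum libraries correlated least with each other among the 10 tissues (Spearman 0.902 to 0.973). The shared spread may thus be too small for ileum, which was not tested. Ileum had 1281 calls without male A and 1068 without the lactating cow, in place of 4005. Adipose tissue had 709, 1108, 1150 and 1099 calls without male A, male B, the lactating cow and the dry cow, in place of 1934. The larger side there was the females with all animals, and the males without male A (375 against 334), male B (608 against 500) or the lactating cow (583 against 567). Heart had 23 genes higher in males without male B, 54 without the lactating cow and 54 without the dry cow, in place of 510. Lung had 20 without the lactating cow (against 39 higher in females), 44 without male A (against 45), 134 without male B and 1144 without the dry cow, in place of 215. Kidney had 63, 74, 70 and 68 genes higher in males without male A, male B, the lactating cow and the dry cow, in place of 154. Muscle had 28 without either male and 39 without the lactating cow, in place of 63, and liver had 32 without male A and 22 without the lactating cow, in place of 54. Frontal cortex had 13, 20 and 54 without male A, the lactating cow and the dry cow, in place of 34, and 103 higher in males and 70 in females without the filter on low values. Spleen had 34 without the lactating cow in place of 98, and rumen 85 without male B in place of 34. Females also became the larger side in rumen without the lactating cow (41 against 19) or the dry cow (24 against 13), and in spleen without the dry cow (81 against 38). Within the libraries that held traces of liver and rumen genes, which leaves 1 female in 7 of the 10 tissues, ileum had 665 genes higher in males and 515 in females, adipose tissue 596 and 645, heart 64 and 11, lung 31 and 57, kidney 84 and 37, and spleen 47 and 28. Quantile normalization changed the split to 2035 and 1908 in ileum, 1060 and 821 in adipose tissue, 51 and 77 in heart (median shift of all genes -0.15), 65 and 34 in kidney, 75 and 94 in spleen, 90 and 84 in muscle, 40 and 38 in liver and 16 and 43 in rumen. Rescaling gave 1014 and 720 in adipose tissue, 257 and 81 in lung, and 113 and 51 in spleen.

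**Figure D4:**
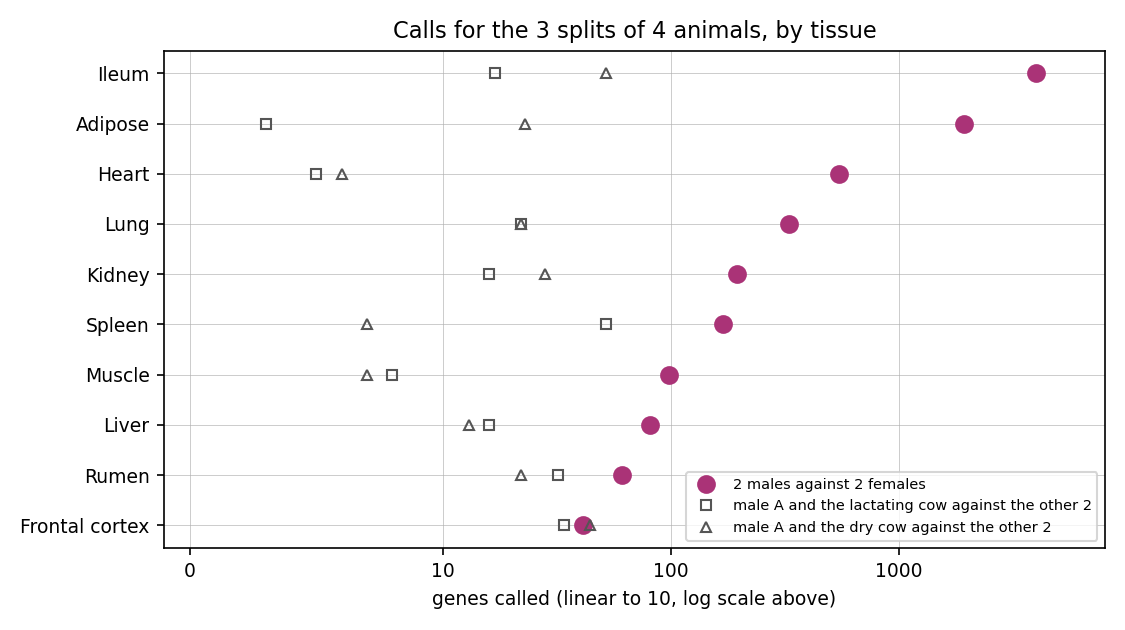
Genes called between 2 animals and the other 2 in each of 10 tissues (x axis, number of genes, linear to 10 and log scale above). Filled circles give males against females and open symbols the other 2 ways to split the 4 animals. Ileum has 4005 calls by sex against 17 and 52 for the other splits, which mix the sexes in each group and so add male-female differences to the spread.

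The sex difference of a tissue was tested against the mean sex difference of the other 9 tissues. It differed for 3672 genes in ileum and 2044 in adipose tissue, and for 25 (heart) to 112 (lung) genes in the other 8 tissues. The 510 genes higher in male hearts thus came with 25 genes for which heart stood apart from the other tissues. Few genes went the same way widely: 3784 genes were higher in males in at least 1 tissue, 25 in at least 5 and none in all 10, and for females these counts were 2747, 4 and none. No gene was higher in all 20 male libraries than in all 20 female libraries, or lower in all 20. Without gene names or chromosomes, sex-linked genes were not looked at, and the sex labels were not checked by them. The counts without an animal ran from 1842 (without the lactating cow) to 6127 (without the dry cow) over all tissues, in place of 6160, with 2021 without male A and 3705 without male B.

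With the animal as the replicate, 121 genes were higher in the 2 males and 21 in the 2 females over the mean of 10 tissues. The higher genes had a median difference of 0.73 on the log2 scale (0.48 to 1.59). Ileum was the label with the highest mean for 70 of the 121 (57.9%) and adipose tissue for 15 (12.4%), against 7.25% and 3.29% of all genes tested. The limma fit had 4 animal means, and the count of both sides, 142, became 63 without male A, 10 without the lactating cow (9 of them higher in females) and 1 without the dry cow, also higher in females. With medians over the tissues limma called 0 genes, and 2468 had an unadjusted p under 0.05. Without the filter on low values it also called 0, with 3761 genes at an unadjusted p under 0.05.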

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

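The tests of explanations in this part were all chosen after the result was seen. Chance marks about 1 in 20 groups of 4 as having a library far from the rest.

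The male minus female difference of a tissue differed from the mean of the other 9 tissues, by a test of that difference, for 3672 genes in ileum, 2044 in adipose tissue, 112 in lung, 90 in spleen, 51 in muscle, 49 in rumen, 43 in frontal cortex, 42 in kidney, 32 in liver and 25 in heart.

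With all libraries, the 4005 calls between males and females in ileum stand above those of the other tissues, but adipose tissue has more without the lactating cow (1150 against 1068) and among libraries that hold the traces (1241 against 1180). Against 1 library as the whole cause, there were 1803 calls, 1729 of them among the 4005, without the ileum library of male A, whose score of adipose-enriched genes was 3.19 against 1.42 to 1.88 in the other 3. Against scaling as the whole cause, 3334 of the 4005 were also called, in the same direction, after quantile normalization. Against the second group of libraries by shared traces as the whole cause, there were 1180 calls, 1118 of them among the 4005, in libraries that hold the traces, although 1803 and 1180 lie far below 4005. A different mix of tissue layers in the ileum samples is a candidate explanation that stays open. Genes of kidney, liver and rumen had medians below the 0.14 of all genes. Genes higher in spleen had a median of 0.34, but they also lay above all genes in liver (0.32 against 0.09, and 0.17 against 0.09 without male A), and in ileum they had 0.05 against 0.03 without the lactating cow, so this value does not decide it. Sex itself was not tested apart from the animals and stays open too. A spread in ileum above the shared estimate was not tested either. With the shared spread 5828 ileum genes had an unadjusted limma p under 0.05, and with ileum fitted alone 2802. Leaving out the lactating cow and keeping only libraries with traces both take the same library from ileum and from adipose tissue. They are not separate checks there.

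Summed over 10 tissues there were 7459 calls by sex, and the other splits of the 4 animals gave at most 224. The other splits put a male and a female in each group. Any difference between males and females then adds to their spread and lowers their calls, so the low counts do not bear on its cause. The real one was the only 1 of 3 splits to reach its count, and 3 splits are too few for a share under 0.05.

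In 4 of 48 groups of 4 libraries 1 library stood apart, where about 2.4 would come from chance if the values were independent. Median correlations within a tissue are not independent, as they share pairs of libraries. The frontal cortex library of male B had a median Spearman correlation of 0.987 with the other cortex libraries, against 0.985 for each of those. The heart library of male B had 0.976, against 0.979 to 0.980. The rumen library of male A had 0.979, against 0.981 for each of the rest. The heart library of male B also had 9566 FPKM of ENSBTAG00000045789, against 12581 to 12864 in the other 3.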

How the results depend on the processing

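The settings that leave out libraries by traces, the ileum library of male A or the leading lactating genes, quantile normalization of the glands, the fit without lymphocytes or block, and the block in the models of sex were chosen after seeing the data. Of the 201 values of the main counts under other settings, 145 stayed within 1.5 times, 36 rose and 20 fell, and of 88 without an animal 74 stayed within 1.5 times and 14 fell. Of the 619 values per direction or single tissue, 415 stayed within 1.5 times, 86 rose and 118 fell, and of the 314 without an animal 204 stayed, 19 rose and 91 fell. The larger side of a pair of opposite counts turned in 29 of 332 pairs, 10 of them without an animal, over 13 comparisons. The causes were not tested unless stated.

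With a pseudocount of 0.1, which enlarges differences of low genes, the calls rose to 1579 in adipose tissue, 3961 in frontal cortex, 2309 in heart, 2151 in ileum, 2225 in kidney, 2908 in liver, 1948 in lung, 4367 in muscle, 1267 in ovary, 1679 in rumen, 2260 in spleen and 1371 in uterus. The larger side turned in heart (899 higher and 1410 lower), liver (1039 and 1869), and by sex in frontal cortex (2 in males and 8 in females) and rumen (20 and 25). Lactating and dry glands then had 163 and 5974 higher genes, and the animal means 82 calls.

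With no minimum difference there were 8776, 12394, 13130, 10909, 11017, 13768, 10840, 14195, 7966, 11430, 11931 and 7969 calls in the same tissues, 6236 genes higher in heart and 1717 in muscle, and 1969 in rumen and 7564 in ileum. Lower genes became the larger side in adipose tissue, heart, liver and rumen. With a difference of at least 1 there were 2968 calls by sex within tissues, 1533 in ileum and 710 in adipose tissue, where males became the larger side (397 and 313), as females did in rumen (15 and 22). Fitted alone each tissue gave 0 limma calls by sex, with 1120 to 3494 genes at an unadjusted p under 0.05.

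Quantile normalization turned the larger side in muscle (752 higher and 373 lower), in the glands, and by sex in adipose tissue (1060 in males and 821 in females), heart (51 and 77), rumen (16 and 43) and spleen (75 and 94). It gave 1125 calls in muscle, 1586 and 1379 genes higher in heart and muscle, 1875 and 2077 in rumen and ileum, 85 between animal means, and 448 and 429 in the lactating and dry glands. Rescaling turned heart (528 higher and 806 lower) and adipose tissue by sex (1014 and 720), and gave 237 calls between animal means and 6058 genes higher in the dry gland. Animal medians gave 0 calls, and so did no filter on low values, with 2468 and 3761 genes at an unadjusted p under 0.05.

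Without the 10 libraries that lack liver and rumen traces there were 3012 calls by sex, 1180 in ileum, 1241 in adipose tissue, 31 higher in males and 57 in females in lung, and 2315 for the difference between tissues. Ileum had 1803 without its library of male A. Without the 10 leading lactating genes, 387 genes were higher in the lactating and 821 in the dry gland.

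The larger side by sex turned in adipose tissue, lung, rumen, spleen and the animal means without 1 or another animal. Leaving out each animal gave 2702 to 8664 calls by sex within tissues, 1068 to 5304 in ileum, 709 to 1150 in adipose tissue, 1842 to 6127 for the difference between tissues and 1 to 161 between animal means. A lone library then took the spread of the other groups.

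With the animal as a replicate block, 3128 and 818 genes were higher in heart and muscle and 994 and 4425 in rumen and ileum. With the animal as a random block there were 7563 calls by sex within tissues, 4046 in ileum and 1956 in adipose tissue, and 6563 for the difference between tissues, or 6739 with the animals as fixed terms. None of these blocks moved a count of a tissue by over 1.5 times. Within a tissue each library comes from a different animal, so the random block could hardly change the calls by sex there. Those counts do not test whether the few animals per sex are enough. Lower genes of ileum and lung went from 23 and 28 to 37 and 42 without the lymphocyte library, and to 44 and 47 with the block as well, so on the same libraries the block moved them by less than 1.5 times. With only the 10 tissues of all 4 animals, lower genes rose in adipose tissue (226), ileum (77), lung (120), rumen (327) and spleen (347). Set tests of the gene lists and the alternative without milk protein genes were not run, as identifiers carry no names. Without read counts, no limit of detection is given.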

Other observations

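Some genes were shared by a few tissues rather than held by 1. A set of 545 genes was enriched in a pair of labels and 198 in a group of 3, each at least 4 times every label outside the group. After kidney with liver (92) and heart with muscle (76), the pairs with most genes were frontal cortex with kidney (23), ileum with kidney (20), and ileum with liver, ileum with rumen and frontal cortex with uterus (19 each). Ileum, lymphocytes and spleen shared 40 genes as a group of 3, and ileum, kidney and liver 25. Ovary and uterus, whose profiles were the closest of any 2 tissues with replicates (0.918), shared 7.

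Lymphocytes had 150 enriched genes, which held 1.45% of their FPKM (62 genes with 1 FPKM added to each mean, 227 with a minimum mean of 0.1 FPKM), and the dry mammary gland had 50, which held 2.75% (76 genes without the lactating cow). The 34 enriched genes of the lactating gland held 75.4%. These labels have 1 library each. In scores of other tissues' enriched genes, 11 of 140 groups of 4 libraries had a library far apart, where about 7 would come from chance. Among them, the rumen library of male A had a score of adipose-enriched genes of 2.38 against 1.70 to 1.80, and 6 concerned genes of the lactating gland.

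Of the tests that follow, that of a few genes taking most of the FPKM was set before its result was seen and the others after.

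Transcripts of very abundant, restricted genes appeared as traces in libraries of other tissues. The 18 liver genes stood at 61.0 to 1340 ppm of their liver level in 37 libraries and at 0 to 33.3 in 10 others, and the 10 rumen genes at 79.6 to 777 and at 0 to 6.51. These 10 libraries were the lymphocyte library and 9 of the lactating cow. The 7 leading genes of the lactating gland were all present in 16 of 45 libraries from other tissues, 11 of them of the dry cow, with a median of 154 ppm.

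Reads exchanged between libraries handled together may account for these traces: in the 16 libraries the 7 genes kept the proportions of the lactating gland, with a median SD of log2 ratios of 0.124, against 0.674 for the proportions of the dry gland. RNA of the animal's own organ as the whole source is argued against by 2 libraries of males that hold all 7. Low expression set by the animal is argued against by the muscle and rumen libraries of the lactating cow, whose liver traces were at least 13.3 times the highest of that animal's low libraries. Its lactating gland, left out of that test, was 3.54 times as high. The labels give no pooling or lane, so which libraries shared a run stays open, and no biological explanation was tested beyond these.

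The excess of genes lower in the lactating than in the dry gland may come from a few genes taking most of the FPKM. Without the 10 most abundant genes of the lactating library, and with both libraries rescaled, 821 genes in place of 3437 were at least 4-fold higher in the dry gland, 387 were higher in the lactating gland, and the median log2 ratio was -0.37. A general difference between the 2 cows is argued against as the whole cause of the 3437, since they differed in at most 381 genes in 1 direction in any of 12 other tissues. The medians over these tissues were 19 genes higher in the lactating cow and 30 in the dry cow. The maximum was in ovary, with 254 and 381. Against the 448 and 429 of the glands after quantile normalization, the comparison does not decide. The state of the gland and a difference between the cows in this gland alone stay open and were not tested, as there is 1 library of each.

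Other splits of the libraries were counted for each model, the real one included. For adipose tissue, frontal cortex, ileum, kidney, liver, lung, muscle and spleen, only 1 of 100 splits, the real one, reached the real count. The share is under 0.05, over splits of the 47 libraries. The other splits mostly mixed tissues within a group, which adds the differences between tissues to the spread. The share therefore shows that the labels group like libraries, and it does not exclude chance for single genes. The real counts were 699, 2416, 1124, 1244, 1399, 974, 1990 and 1058, and the highest of the other splits 450, 1226, 163, 562, 447, 635, 779 and 55. For heart 3 of 100 splits reached the 985 calls, the highest other with 1283, and for rumen 2 of 100 reached 787, the highest other with 1266. These shares are also under 0.05, although other splits gave more calls than the real one. For heart against muscle 1 of 35 splits reached 3931 calls, with 1 as the highest other, and for rumen against ileum 1 of 35 reached 5376, with 0 as the highest other. Among the 8 splits of each that part every animal's pair, the highest other count was 0. These other splits also mixed both tissues in each group, so the same limit holds.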
